A study of Ambystoma mexicanum with 44 samples.

How the data were processed

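The samples were skin of axolotls (Ambystoma mexicanum) taken from full thickness punch wounds of the flank and from forelimbs amputated above the elbow, with the humerus trimmed back, with or without cutting of the brachial nerves. Per the labels, the epidermis and the cells adhering to it were collected, 2 harvested samples of an animal were pooled into 1 RNA sample, and each group held 4 biological replicates. RNA was extracted with Trizol and cleaned on RNeasy columns, and biotin-labelled cRNA was hybridised to an Affymetrix array made for this species. The 44 arrays formed 11 groups of 4. The flank and the innervated limb had samples at days 0, 1, 3 and 7, and the denervated limb at days 1, 3 and 7. The labels gave no scan date, hybridisation batch or sex, so no batch could be examined.

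The values deposited by the authors are log2 expression values with 2 decimals, between 2.41 and 15.04, and the array medians lay between 5.61 and 5.72. The submitters' processing notes name RMA and limma without saying how either was used. No further normalization, floor or filter was applied for the main results. The alternative planned for values on a linear scale was not run, because the values are already logarithms. Of 20080 probe sets, 45 are control probe sets for spiked and labelling RNA, and the other 20035 were tested. A gene symbol was attached to 10951 probe sets, covering 8639 genes, and 9084 probe sets were unnamed here. Of the 1740 genes with more than 1 probe set, 199 had probe sets called in opposite directions in at least 1 comparison. The number of arrays limits the precision, and the median SE of a log2 difference over probe sets was 0.123 for a difference of 2 groups and 0.174 for a difference of differences.

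Each probe set was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, a common variance over the 44 arrays (33 residual degrees of freedom) and empirical Bayes moderation. Adjusted p-values are Benjamini-Hochberg values over the 20035 probe sets of a comparison, all tests are two-sided, and a probe set was called at an adjusted p under 0.05. Rose, fell and changed are used for called probe sets. There were 19 comparisons set before the data were examined. These were each series against day 0 on each later day, innervated against denervated limb on each later day, the difference between each limb series and the flank in their changes from day 0, and limb against flank at day 0. Another 3 comparisons, of the difference between innervated and denervated limb on 1 day against that on another, were added after the data were seen. Both limb series were compared with the same 4 uninjured innervated limb arrays, because no denervated samples of day 0 are among the labels. Changes of the limb series therefore share the error of those arrays. To measure this, limma was run on 20 sets of simulated values without any change, and the 4 day 0 arrays were also split 2 and 2 between the series in 6 ways.

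Genes were named by a rule set beforehand. In the comparisons of innervated with denervated limb, up to 10 genes with the largest positive and 10 with the largest negative difference were eligible, if the probe set had 1 gene symbol, an adjusted p under 0.05 and no overlap between the 4 values of one group and the 4 of the other. A gene was represented by its probe set with the highest mean over the arrays. For changes from day 0 the limit was 5 in each direction, and for limb against flank at day 0 it was 10. For differences of changes it was 10 in each direction without the condition on overlap. Up to 4 members of each gene list with the smallest adjusted p were eligible in each comparison, and any member could be given where it did not pass.

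The 26 gene lists, for cell types, structures and processes, were written from general knowledge before the data were examined. A list was tested when at least 5 of its genes were measured, which left out the keratins (2 of 27 genes measured) and kept 25 lists. Each list was tested with limma's camera at its preset inter-gene correlation of 0.01, two-sided, on the 1 probe set per gene described above, and the 550 tests of 25 lists in 22 comparisons were adjusted together. Of these, 196 were called. Camera was repeated with a correlation estimated from the data, with which 29 of the 196 also passed, and limma's fry, which asks whether the genes of a list move on balance in a direction without comparing them with other genes, called 195 of the 550. For each list the number of members called was counted after adjustment over all probe sets and again after adjustment over the list alone. Lists of further genes, for cholesterol synthesis, osteoclasts, sugar nucleotide synthesis and retinoid metabolism, were made after the data were seen and are used only in the closing section.

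The procedure was tested on values drawn from the mean and the spread of each probe set, with known changes added. For innervated against denervated limb at day 7, 50 probe sets each were shifted by 1.5-fold, 2-fold, 3-fold and 4-fold, and 72%, 96%, 94% and 98% of them were called, with 6.25% false calls. For a difference of changes at day 3 the recovery was 34%, 70%, 90% and 98%, with 5.19% false calls. A list shifted by 1.5-fold was called and none of the other lists were. The simulated probe sets varied independently of each other, so this does not test false list calls among correlated genes.

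Alternatives planned before the data were examined were a repeated quantile normalization, subtraction of each array's median, array weights, an intensity trend with a robust prior, removal of the dimmest 25% of probe sets by mean value, the arrays of a comparison alone, replicate number as a block, each array left out in turn, fry and an estimated correlation for lists, the mean over all probe sets of a gene, a 2-fold minimum for overlaps, and a direct difference between limb and flank. The mean of the skeletal muscle list as a covariate, and the removal of the 3 arrays with the highest muscle signal, were added after the data were seen.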

Results

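An axolotl regrows an amputated limb as long as the stump keeps its nerve supply, whereas a denervated stump and a flank wound heal over without regrowth. The comparisons address how the wound epidermis of these 3 settings differs in gene expression. Epidermis with its adhering cells was profiled on 44 arrays, in 11 groups of 4 biological replicates, each a pool of 2 harvested samples from an animal. Values are deposited log2 expression levels, differences are log2 differences with their SE, and each group mean rests on n = 4 arrays. Except in differences of changes, the genes named from the largest differences had no overlap between the 4 values of one group and the 4 of the other. Component 1 of a principal component analysis held 26.3% of the variance and component 2 held 24.5%. Within each series the days sampled occupied separate places on the plane of these components. At day 7 the flank arrays lay between 20.1 and 25 on component 1, the innervated limb arrays between 34 and 43.4, and the denervated limb arrays between 39.5 and 49.1.

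**Figure D1:**
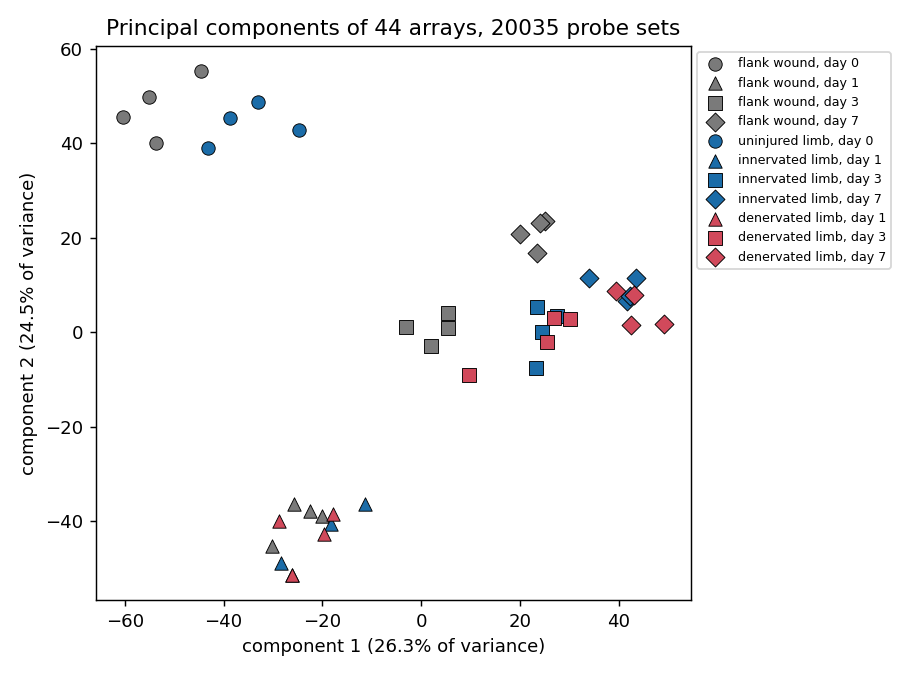
Each point is an array placed by its scores on component 1 (x axis, 26.3% of the variance) and component 2 (y axis, 24.5%), with colours for flank, innervated limb and denervated limb and markers for the day. Day 1 arrays lie between −51.4 and −36.3 on component 2, and uninjured arrays between 39 and 55.3.

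At day 1 after amputation, the innervated limb epidermis gained transcripts of secreted matrix proteins and of their inhibitors. TIMP1, an inhibitor of matrix metalloproteinases, rose by 6.86 ± 0.42, a 116-fold difference (adjusted p = 1.61e-15). The lubricating proteoglycan PRG4 rose by 6.67 ± 0.32, tenascin C (TNC), an adhesion-modulating matrix protein of wounds and embryos, by 5.50 ± 0.20, and thrombospondin 1 (THBS1) by 5.43 ± 0.26. KIT, the receptor for stem cell factor in pigment cells, fell by 2.81 ± 0.26. The calcium-sensing receptor relative GPRC6A (difference −2.84 ± 0.24) and the potassium channel subunit KCNAB1 (−2.90 ± 0.30) also fell. Of the matrix and fibroblast list, 21 of 44 members rose, 23 when adjusted over the list alone, and its median was 0.923 (camera adjusted p = 1.56e-08, adjusted p = 0.199 with an estimated correlation). That median was 0.422 without the 3 arrays of highest muscle signal. The collagen crosslinking enzyme LOXL2 rose by 3.40 ± 0.31. Of 25 matrix proteases and inhibitors 10 rose and 2 fell (10 and 2 when adjusted over the list alone), with MMP2 up by 4.69 ± 0.30 (camera adjusted p = 0.00081, adjusted p = 0.0686 with an estimated correlation). The basement membrane and hemidesmosome list had 11 members up and 1 down of 28, and 12 and 1 when adjusted over the list alone (adjusted p = 8.54e-05, 0.123 with an estimated correlation). The rise of this list was uneven over arrays, with means from −0.356 to 0.574 at day 1 and from −0.653 to −0.477 at day 0. Its member COL7A1, the anchoring fibril collagen, rose by 2.38 ± 0.22, and COL17A1 of the hemidesmosome by 1.49 ± 0.11. In total 2946 probe sets rose and 4257 fell, 36.0% of those tested.

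Signalling, cytoskeletal and metabolic genes moved on the same day. TGF-beta and activin signalling had 10 of 26 members up and 1 down, in both adjustments, and the list passed with either correlation (adjusted p = 7.55e-05 and 0.0192). Among these, PMEPA1, a target and brake of the pathway, rose by 4.32 ± 0.20 and the transcriptional repressor SKIL by 1.88 ± 0.14. Actin and migration genes had 22 of 48 up and 2 down, 23 and 2 when adjusted over the list alone (adjusted p = 7.94e-05, 0.00484 with an estimated correlation), and talin (TLN1) rose by 1.56 ± 0.14. Glycolysis and hypoxia genes had 14 of 21 up and 1 down, 15 and 1 when adjusted over the list alone, with the lactate transporter SLC16A1 up by 3.30 ± 0.26 (adjusted p = 4.63e-06, 0.0775 with an estimated correlation). Chaperones of the endoplasmic reticulum rose, HSPA5 by 2.60 ± 0.27 and CRELD2 by 2.15 ± 0.15, in a list with 15 of 42 up and 6 down in both adjustments (adjusted p = 0.00981, 0.287 with an estimated correlation). Ribosome biogenesis and proteasome genes had 20 of 56 up and 5 down, 21 and 5 when adjusted over the list alone (adjusted p = 0.000655, 0.395 with an estimated correlation). Immediate early and wound-activated transcription factors had 8 of 24 up and 1 down in both adjustments (adjusted p = 0.0107, 0.545 with an estimated correlation). Limb development and blastema genes had 13 of 44 up and 4 down in both adjustments (adjusted p = 0.00081, 0.0715 with an estimated correlation). The stem cell transcription factor SALL4 rose by 5.07 ± 0.17 and BMP2 by 2.51 ± 0.15.

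Cell division genes fell, and myeloid, erythrocyte and muscle genes rose. Of 67 mitosis and G2/M genes 43 fell and 1 rose, 46 and 1 when adjusted over the list alone, with a median of −0.755 (camera adjusted p = 2.7e-05, adjusted p = 0.67 with an estimated correlation). The proliferation antigen MKI67 fell by 1.01 ± 0.17 and the spindle protein ASPM fell by 1.84 ± 0.30. Of 27 myeloid genes 12 rose and 1 fell in both adjustments (adjusted p = 0.000169, 0.383 with an estimated correlation), and NCF1, a subunit of the phagocyte oxidase, rose by 3.91 ± 0.26. The median of the myeloid list went from 0.408 to 0.267 without innervated day 1 replicate 4 and to 0.147 without the 3 arrays of highest muscle signal. Of 10 erythrocyte and thrombocyte genes 7 rose in both adjustments, among them RHAG by 2.46 ± 0.37 (adjusted p = 0.00083, 0.256 with an estimated correlation). Of 39 skeletal muscle genes 19 rose, 23 when adjusted over the list alone, with a median of 1.89 (adjusted p = 7.75e-05, 0.641 with an estimated correlation). The median of the skeletal muscle list was 1.24 without innervated day 1 replicate 3, and its call ended without the 3 arrays of highest muscle signal (adjusted p = 0.398). Muscle signal was uneven, and the list means of innervated day 1 replicates 3 and 4 (2.77 and 3.02 above the mean of all arrays) and of denervated day 3 replicate 3 (2.85) were the highest of the 44.

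The other lists did not pass as lists at day 1. Among the epidermal differentiation genes 10 of 21 rose and 7 fell in both adjustments (camera adjusted p = 0.381). The desmosomal cadherin DSC2 rose by 1.25 ± 0.11, and the barrier regulator GRHL3 fell by 1.83 ± 0.15. Of the keratins, KRT18 fell by 0.96 ± 0.15 and KRT8 fell by 0.46 ± 0.077, the only 2 measured. The epithelial sodium channel subunit SCNN1B fell by 2.0 ± 0.26, in an ion transport list with 2 of 11 up and 5 down in both adjustments (adjusted p = 0.372). DNA replication and G1/S genes had 15 of 52 down and 1 up, 14 and 1 when adjusted over the list alone (adjusted p = 0.112). Inflammatory mediators had 5 of 24 up and 2 down, 4 and 1 when adjusted over the list alone (adjusted p = 0.106), and the prostaglandin synthase PTGES rose by 2.19 ± 0.36. Antigen presentation genes had 3 of 8 down, 4 when adjusted over the list alone (adjusted p = 0.378), and no lymphoid gene of 6 passed (adjusted p = 0.638). Nerve and Schwann cell genes had 7 of 19 up and 2 down in both adjustments (adjusted p = 0.0792), endothelial genes 4 of 15 up, 3 when adjusted over the list alone (adjusted p = 0.0856), and cartilage and bone genes 3 of 20 up in both adjustments (adjusted p = 0.218). Oxidative phosphorylation genes had 12 of 50 down and 4 up, 11 and 4 when adjusted over the list alone (adjusted p = 0.285). Cytosolic ribosomal protein genes had 7 of 56 down and 1 up over all probe sets, and no member passed when adjusted over the list alone (adjusted p = 0.169).

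By days 3 and 7 the innervated limb epidermis carried KAZALD1, a secreted protein of the insulin-like growth factor binding superfamily, at levels higher by 7.17 ± 0.37 and 7.93 ± 0.37 than at day 0 (adjusted p = 1.62e-17 and 6.35e-19). SALL4 was higher by 6.53 ± 0.17 and 6.64 ± 0.17, TNC by 6.25 ± 0.20 and 6.59 ± 0.20, and fibronectin (FN1) by 5.09 ± 0.33 and 6.18 ± 0.33. HOPX, a transcriptional cofactor of differentiated epithelium, fell by 2.71 ± 0.26 at day 3, and sepiapterin reductase (SPR), an enzyme of pigment and cofactor synthesis, had a difference of −2.61 ± 0.28. Matrix and fibroblast genes had 17 of 44 members up at day 3 and 25 at day 7, with 17 and 25 when adjusted over the list alone and medians of 0.505 and 0.896. The camera adjusted p was 1.45e-06 and 8.74e-10, and the adjusted p = 0.28 and 0.16 with an estimated correlation. TGF-beta signalling had 14 of 26 up at day 3 and 12 at day 7, 15 and 12 when adjusted over the list alone, and passed with either correlation (adjusted p = 0.00484 on both days with an estimated correlation). Matrix proteases and inhibitors also passed on both days with either correlation (adjusted p = 0.0321 and 0.0229 with an estimated correlation), with 10 of 25 up and 1 down on each day in both adjustments and MMP14 up by 2.50 ± 0.18 and 2.70 ± 0.18. Limb development genes had 11 of 44 up and 2 down at day 3 in both adjustments, with a median of −0.00375, a mean of 0.599 and a test in the direction of the mean (adjusted p = 0.00512, 0.126 with an estimated correlation). With each array left out in turn that median lay between −0.0338 (without innervated day 0 replicate 4) and 0.0217 (without innervated day 3 replicate 1). At day 7 the basement membrane gene LAMA1 was higher by 3.48 ± 0.26 and COL7A1 by 4.67 ± 0.22, in a list with 14 of 28 up and 1 down in both adjustments (adjusted p = 6.91e-06, 0.0775 with an estimated correlation). Ribosome biogenesis and proteasome genes had 27 and 25 of 56 up on the 2 days, 28 on each when adjusted over the list alone (adjusted p = 0.203 and 0.245 with an estimated correlation), and myeloid genes 14 and 14 of 27 up, 16 and 15 when adjusted over the list alone, with 1 down on each day (adjusted p = 0.212 and 0.245 with an estimated correlation).

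Of 67 mitosis and G2/M genes 3 rose and 1 fell at day 7, 3 and 0 when adjusted over the list alone (camera adjusted p = 0.217). Of 52 DNA replication and G1/S genes 11 rose and 3 fell in both adjustments (adjusted p = 0.0328, 0.821 with an estimated correlation). The call of that list ended without innervated day 0 replicates 3 or 4 (adjusted p = 0.0922 and 0.171) or innervated day 7 replicate 1 (0.234), with array weights (0.0628) or without the dimmest 25% of probe sets (0.0886). MYCN, a transcription factor of proliferating progenitors, rose by 3.00 ± 0.24, and CRABP2, which carries retinoic acid, by 2.94 ± 0.21. The limb development list had 12 of 44 up and 2 down in both adjustments and passed with either correlation (adjusted p = 6.48e-05 and 0.028). Of 50 genes of oxidative phosphorylation and the citric acid cycle 22 fell, 23 when adjusted over the list alone (adjusted p = 7.61e-05, 0.355 with an estimated correlation), among them citrate synthase (CS, −0.47 ± 0.055) and SDHB (−0.51 ± 0.067). MYL1, a myosin light chain of fast muscle, fell by 5.95 ± 1.35, and the muscle list had 6 of 39 down, 5 when adjusted over the list alone (adjusted p = 0.0702). The falls of TNNC2 (−4.04 ± 1.22) and CKM (−3.76 ± 1.20) lost their calls without innervated day 0 replicate 2 (adjusted p = 0.0523 and 0.0721). There were 5189 changed probe sets at day 3 and 5336 at day 7.

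In the denervated limb epidermis at day 1 PRG4 rose by 6.96 ± 0.32, TIMP1 by 6.66 ± 0.42 and TNC by 5.48 ± 0.20, and by day 7 KAZALD1 had risen by 8.19 ± 0.37 and SALL4 by 6.75 ± 0.17. Cathepsin K (CTSK), the collagen-degrading protease of osteoclasts, rose by 7.15 ± 0.46 at day 7 (adjusted p = 4.4e-15), and tartrate-resistant acid phosphatase (ACP5), another osteoclast and macrophage enzyme, by 2.60 ± 0.23. CDO1, which oxidises cysteine, fell by 3.69 ± 0.24. Myeloid genes rose over the days, with 11, 15 and 18 of 27 up at days 1, 3 and 7 (13, 17 and 20 when adjusted over the list alone) and 1 down on each day. Their median reached 1.16 at day 7 (camera adjusted p = 1.65e-12, adjusted p = 0.0747 with an estimated correlation), with the phagocyte oxidase subunit CYBB up by 2.81 ± 0.25 and the lysosomal protease LGMN by 1.43 ± 0.11. Matrix proteases and inhibitors had 12 of 25 up and 1 down at day 7, 13 and 1 when adjusted over the list alone, and passed with either correlation (adjusted p = 1.52e-06 and 0.00818). Matrix and fibroblast genes had 24 of 44 up and 1 down, 25 and 1 when adjusted over the list alone (adjusted p = 1.72e-09, 0.167 with an estimated correlation). Of 67 mitosis and G2/M genes 26 fell at day 1 and 31 at day 7, with 1 and 2 up, and 28 and 41 fell when adjusted over the list alone, with a day 7 median of −0.72 (adjusted p = 7.23e-06, 0.641 with an estimated correlation). ANLN, the anillin of the cleavage furrow, fell by 1.61 ± 0.37 and MKI67 fell by 0.71 ± 0.17. The counts of changed probe sets were 6845, 5297 and 5404 at days 1, 3 and 7.

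In flank wounds PRG4 rose by 6.78 ± 0.32 and TNC by 5.47 ± 0.20 at day 1, and the secretory granule protein SCG2 by 5.47 ± 0.38. The long pentraxin PTX3, a matrix-binding defence protein, fell by 5.97 ± 0.86 (adjusted p = 4.76e-07), and the dermal matrix genes MGP and ABI3BP had differences of −4.52 ± 0.74 and −4.46 ± 0.55. Cell division transcripts fell at day 1. Of 67 mitosis genes 47 fell and 2 rose in both adjustments (camera adjusted p = 1.75e-07, adjusted p = 0.57 with an estimated correlation), and of 52 DNA replication genes 27 fell and 3 rose in both adjustments (adjusted p = 2.88e-05, 0.562 with an estimated correlation). The differentiation list had 12 of 21 members up and 4 down in both adjustments (adjusted p = 0.0146, 0.395 with an estimated correlation), with the crosslinking enzyme TGM1 up by 2.76 ± 0.34. With the flank arrays of the 2 days alone the adjusted p of the epidermal differentiation list was 0.0597. Matrix and fibroblast genes went both ways at day 1, 14 up and 11 down of 44 (15 and 11 when adjusted over the list alone). Their median was 0.075, their mean −0.0336 (camera adjusted p = 0.394). By day 7 20 of them were up, 21 when adjusted over the list alone (adjusted p = 1.9e-09, 0.167 with an estimated correlation), and the fibrillar collagen COL11A1 had risen by 6.64 ± 0.18 and KAZALD1 by 8.21 ± 0.37. Basement membrane genes had 9 of 28 up at day 7 in both adjustments (adjusted p = 1.52e-06, 0.0642 with an estimated correlation), with LAMA1 up by 4.46 ± 0.26. Chaperones fell by day 7, with HSP90B1 at −1.73 ± 0.13 and SDF2L1 at −1.28 ± 0.11, in a list with 20 of 42 down and 3 up in both adjustments that passed with either correlation (adjusted p = 1.17e-07 and 0.0236). Of 39 muscle genes 17 were down and 2 up at day 7, 19 and 2 when adjusted over the list alone (adjusted p = 0.00106, 0.703 with an estimated correlation), and TNNC2 fell by 4.99 ± 1.22. With the muscle signal as a covariate the call of the skeletal muscle list ended (adjusted p = 0.801). That covariate is the mean of the same list and removes its signal by construction, so this does not weigh on the fall. The counts of changed probe sets were 8271, 5485 and 4749 at days 1, 3 and 7, and 13418 probe sets changed in at least 1 of the 9 comparisons with day 0.

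**Figure D2:**
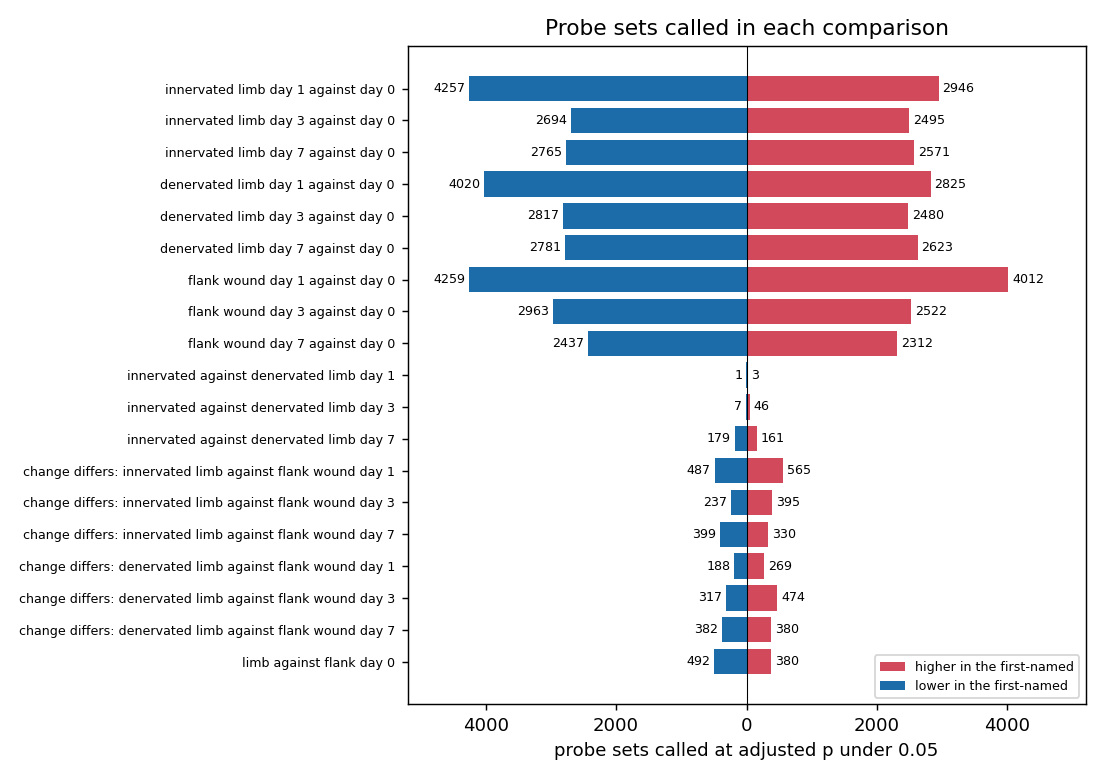
Bars give the number of probe sets (x axis) called higher, to the right, and lower, to the left, at a limma adjusted p under 0.05 in each of the 19 comparisons (y axis). Changes from day 0 involve 4749 to 8271 probe sets, and innervated against denervated limb 4 at day 1, 53 at day 3 and 340 at day 7.

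The limb series shared most of their changes with each other and many with the flank. Innervated and denervated limb had 5834, 4192 and 4120 probe sets called in the same direction at days 1, 3 and 7, with opposite calls of 0, 1 and 1. TIMP1, PRG4 and TNC at day 1 and KAZALD1 and SALL4 at days 3 and 7 were among those higher in both. Across probe sets, which are not independent replicates, the correlation of the limb changes was 0.952, 0.923 and 0.924. The limb series share their day 0 arrays, and simulated values without any change gave correlations of 0.499, 0.501 and 0.495 with no shared calls by limma. Those simulated values hold only error, and their covariance at day 1 was 0.0184, against 0.43 in the data. With the 4 day 0 arrays split 2 and 2 between the series, 4110 to 4311 probe sets were shared at day 1, and at day 3 between 2645 and 2820. The correlation over these splits was 0.846 to 0.889 at day 1, 0.799 to 0.857 at day 3 and 0.811 to 0.861 at day 7. Innervated limb and flank shared 5056, 3132 and 3021 calls in the same direction, against an expectation of 590 both higher and 905 both lower at day 1, with 104, 41 and 40 opposite. Denervated limb and flank shared 5080, 3186 and 3083. All 3 series had 1841 probe sets up and 2753 down at day 1, and 1390 up and 1345 down at day 7.

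At day 1 the innervated and denervated limb differed in 4 probe sets (limma adjusted p under 0.05), 3 higher and 1 lower in the innervated limb, and 1584 had an unadjusted p under 0.05. KRIT1, a regulator of endothelial junctions, was higher by 0.70 ± 0.11 (adjusted p = 0.00342) and HOMER1, a postsynaptic scaffold protein, by 0.70 ± 0.12 (adjusted p = 0.0157). The other two were unnamed here and are given although the naming rule does not cover them, chosen after their values were seen: axo28249-f_at, higher by 1.54, and axo06364-f_at, with a difference of −0.965. The count went to 0 without denervated replicate 1 and was 2 without denervated replicate 2, 1 without denervated replicate 4 or innervated replicate 3, 30 without innervated replicate 1, and 10 and 11 without innervated replicates 2 and 4. With the arrays of the 2 groups alone it was 0, and KRIT1 and HOMER1 had an adjusted p of 0.221 and 0.546. KRIT1 lost its call without denervated replicate 1 (adjusted p = 0.0632), and HOMER1 without denervated replicates 1, 2 or 4 or innervated replicate 3 (0.0641, 0.0664, 0.0645 and 0.196) or without the 3 arrays of highest muscle signal (0.206). With a repeated quantile normalization the share of higher calls went from 75% to 52.9% of a count of 17. No member of any list passed over all probe sets. Nerve and Schwann cell genes were higher as a list, with 3 of 19 called when adjusted over the list alone (camera adjusted p = 0.00081, adjusted p = 0.0944 with an estimated correlation). Among these the myelin gene PMP22 was higher by 1.65 ± 0.34 (adjusted p = 0.0597) and GLDN of the node of Ranvier by 3.00 ± 0.69 (adjusted p = 0.111), neither past the threshold. Epidermal differentiation genes were lower (adjusted p = 0.000563, 0.2 with an estimated correlation), matrix genes higher (adjusted p = 0.000928, 0.545 with an estimated correlation) and mitosis genes lower (adjusted p = 0.00357, 0.812 with an estimated correlation). Without the 3 arrays of highest muscle signal the adjusted p of the nerve and Schwann cell list was 0.696, of the epidermal differentiation list 0.114, of the fibrillar and provisional matrix list 0.986, with the direction of the test reversed, and of the mitosis list 0.188. That removal left innervated replicates 1 and 2, with muscle scores of 0.364 and −0.0476, against denervated scores of 0.225, 1.74, 1.76 and 1.98. It reversed the imbalance in muscle signal and left fewer arrays, so these lost calls do not show that muscle caused the differences. The matrix call also ended without innervated replicate 3 alone (0.356), and the mitosis and G2/M call without denervated replicates 3 or 4 or innervated replicates 2 or 3 (0.19, 0.158, 0.0563 and 0.177).

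At day 3 the innervated and denervated limb epidermis differed in 53 probe sets. GFPT2, which makes glucosamine phosphate for hexosamine synthesis, was higher by 2.4 ± 0.37 (7.14 against 4.74, adjusted p = 0.00124), and UAP1, which makes UDP-N-acetylglucosamine in the same pathway, by 1.30 ± 0.22 (adjusted p = 0.00298). TGM1, the transglutaminase of the cornified envelope, was higher by 1.85 ± 0.35 (adjusted p = 0.00553), the LIM domain junction protein LMO7 by 1.23 ± 0.13 (adjusted p = 2.19e-07) and the membrane raft protein MALL by 1.96 ± 0.31. EREG (epiregulin), a ligand of the epidermal growth factor receptor, was higher by 1.29 ± 0.24, and EIF2AK3, the kinase PERK of the unfolded protein response, by 0.93 ± 0.15. UGDH, which makes UDP-glucuronic acid, was higher by 1.00 ± 0.20 (adjusted p = 0.00866), a call that ended without denervated replicate 3 (adjusted p = 0.111). Epidermal differentiation genes had a median of 0.145 with 1 of 21 called and 3 when adjusted over the list alone (camera adjusted p = 0.000184, adjusted p = 0.167 with an estimated correlation). Mitosis genes had a median of 0.265 with no member called (adjusted p = 1.39e-06, 0.62 with an estimated correlation). Without denervated replicate 3 the median of the epidermal differentiation list was 0.055, and without denervated replicates 1 and 2 that of the mitosis and G2/M list was 0.129 and 0.452. Endothelial genes were lower as a list (adjusted p = 0.00195, 0.2 with an estimated correlation). Skeletal muscle genes were lower with a median of −1.08 and no member called (adjusted p = 5.02e-09, 0.395 with an estimated correlation), and that call ended without denervated replicate 3 (adjusted p = 0.647) and without the 3 arrays of highest muscle signal (0.583). In total 46 probe sets were higher and 7 lower in the innervated limb, 28 in all without denervated replicate 3 and 33 without innervated replicate 2. Fitted with the arrays of the 2 groups alone, 11 passed, and MALL, EREG, EIF2AK3 and UGDH did not (adjusted p = 0.214, 0.149, 0.134 and 0.214). The UGDH call also ended without the 3 arrays of highest muscle signal (adjusted p = 0.108).

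At day 7 the innervated limb epidermis exceeded the denervated one in cell division genes. The S phase gene TK1 (thymidine kinase) was higher by 1.76 ± 0.41 (6.27 against 4.51, adjusted p = 0.0189), cyclin B1 (CCNB1) by 1.43 ± 0.37 (8.64 against 7.20, adjusted p = 0.0337) and the cyclin-dependent kinase subunit CKS2 by 0.83 ± 0.15 (adjusted p = 0.00178). Of 67 mitosis and G2/M genes 21 were higher and none lower, 49 when adjusted over the list alone, with a median of 0.89 (camera adjusted p = 2.9e-37, adjusted p = 0.0858 with an estimated correlation). DNA replication and G1/S genes had 17 of 52 higher, 31 when adjusted over the list alone, with a median of 0.544 (adjusted p = 2.25e-23, 0.0857 with an estimated correlation). MYCN was higher by 1.17 ± 0.24. CRABP1, a retinoic acid binding protein of the blastema list, was higher by 2.38 ± 0.49 (adjusted p = 0.0072), a call that ended without innervated replicate 1 (adjusted p = 0.0872) and with the arrays of the 2 groups alone (0.166). The calls of single cell division genes rested on few arrays. TK1 lost its call without denervated replicate 2 or innervated replicate 1 (adjusted p = 0.082 and 0.145), and CCNB1 without denervated replicates 2, 3 or 4 or any of innervated replicates 1, 2 and 3 (adjusted p between 0.0582 and 0.165). CKS2 and MYCN kept theirs in each of these. Over both cell division lists the number of members called fell from 38 of 119 to 1 without innervated replicate 1, while their median went from 0.715 to 0.583.

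**Figure D3:**
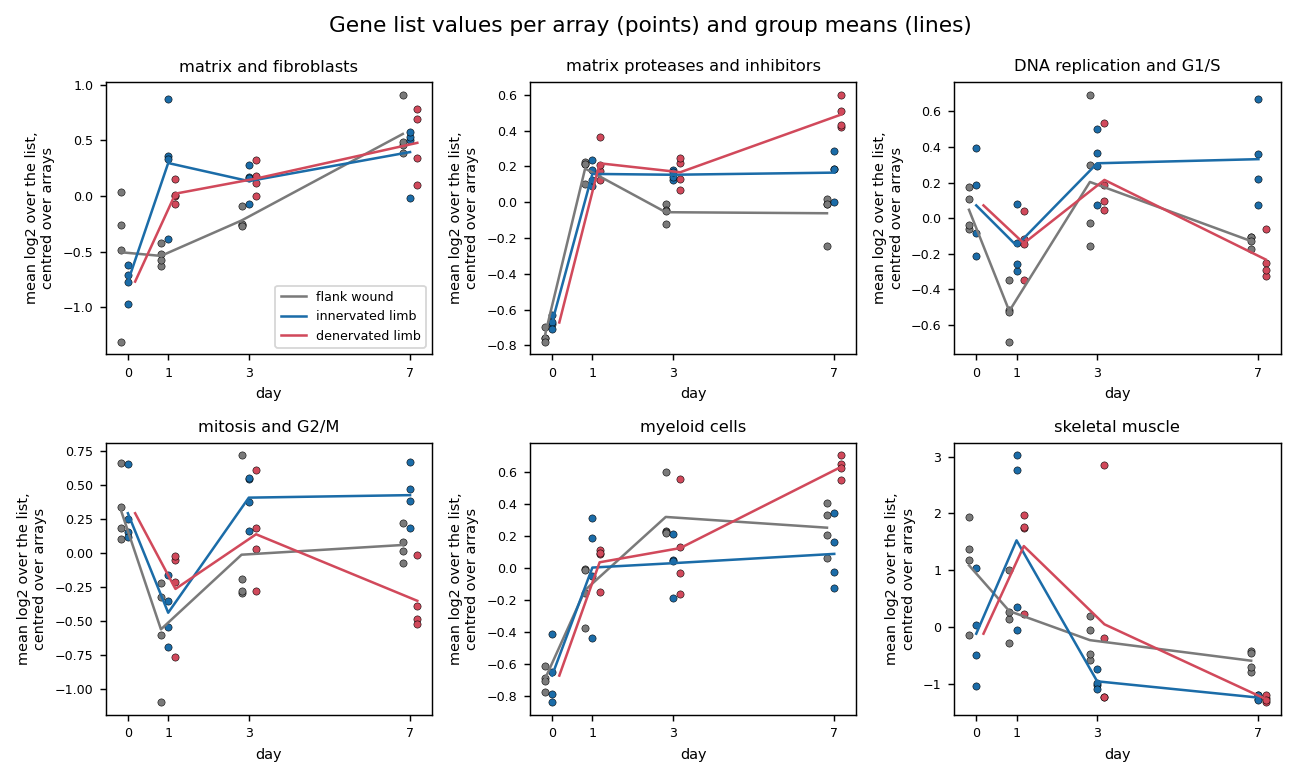
Each panel plots for 1 gene list the mean log2 level of its members, centred over all arrays (y axis), by day (x axis) for flank, innervated and denervated limb, with a point per array and lines through group means; the denervated line starts at the limb's day 0. At day 7 the mitosis and G2/M mean is 0.182 to 0.669 in the innervated and −0.524 to −0.0123 in the denervated limb, and the myeloid mean −0.126 to 0.344 and 0.554 to 0.705.

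In the innervated limb at day 7 CTSK was lower by 4.13 ± 0.46 (8.36 against 12.5), a 17.4-fold difference (adjusted p = 9.55e-07). ACP5 was lower by 1.44 ± 0.23 (adjusted p = 0.000586), brain-type creatine kinase (CKB), which osteoclasts also carry, differed by −1.55 ± 0.25 (adjusted p = 0.000603), and the lysosomal calcium channel MCOLN3 by −1.35 ± 0.13 (adjusted p = 5e-08). PLEK (pleckstrin) of blood cells was lower by 1.07 ± 0.23 and the proton pump subunit ATP6V1E1 of the ion transport list was lower by 0.66 ± 0.10. Of 27 myeloid genes 4 were lower, 17 when adjusted over the list alone, with a median of −0.668 (camera adjusted p = 1.91e-12, adjusted p = 0.0758 with an estimated correlation). Matrix proteases and inhibitors had 4 of 25 lower, 6 when adjusted over the list alone (adjusted p = 0.00217, 0.0873 with an estimated correlation). MMP2 was lower by 1.47 ± 0.30 (adjusted p = 0.00628), a call that ended without innervated replicate 1 (adjusted p = 0.0763) and with the arrays of the 2 groups alone (0.0735). CALB1, a calcium buffer, was lower by 1.52 ± 0.29 and also lost its call with the latter (adjusted p = 0.0845). Ribosome biogenesis and proteasome genes were higher with a median of 0.0725 (adjusted p = 6.68e-05, 0.296 with an estimated correlation). Epidermal differentiation genes had a median of 0.0125 (adjusted p = 0.924). In total 161 probe sets were higher and 179 lower in the innervated limb. The count was 72 without innervated replicate 1, 183 without innervated replicate 2, and 220, 172 and 182 without denervated replicates 1, 2 and 3.

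**Figure D4:**
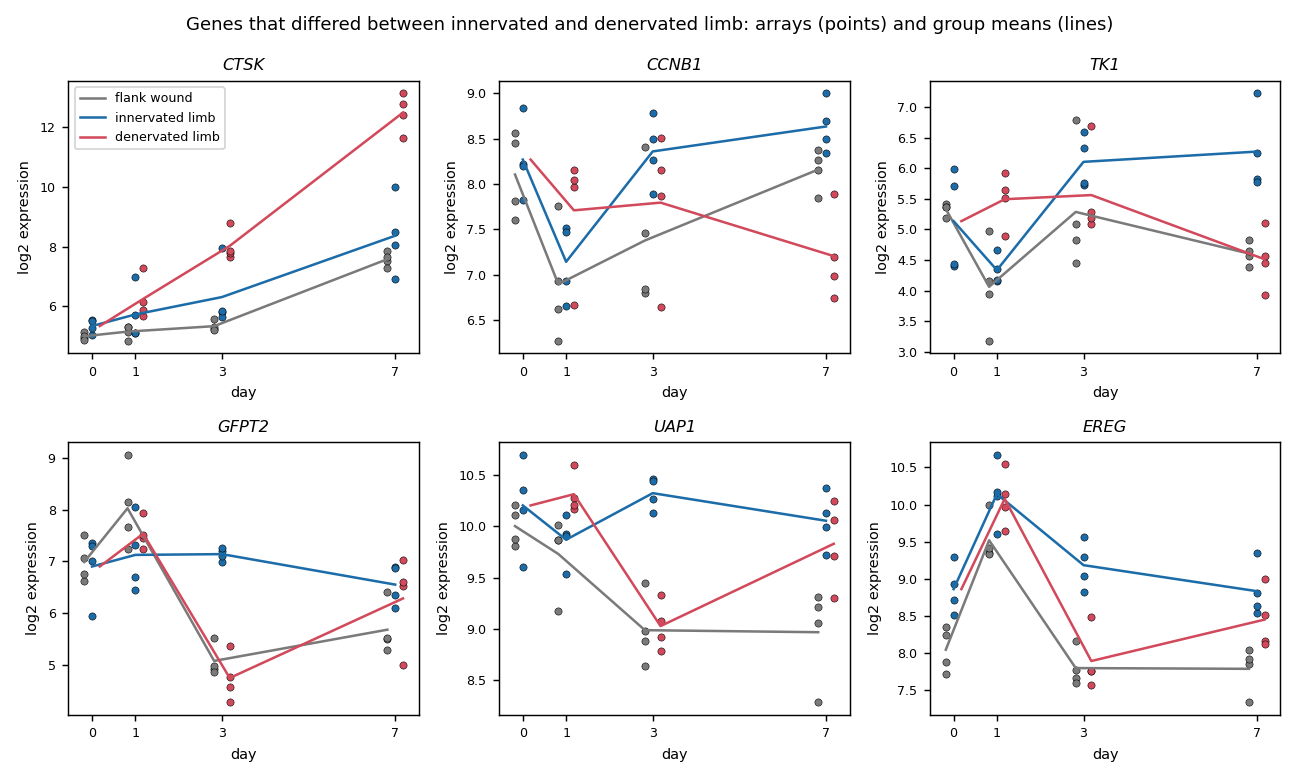
Each panel plots the log2 expression level of 1 gene (CTSK, CCNB1, TK1, GFPT2, UAP1 and EREG, y axis) by day (x axis) in flank, innervated and denervated limb, with a point per array and lines through group means. CTSK at day 7 averages 12.5 in the denervated limb, 8.36 in the innervated limb and 7.58 in the flank, and GFPT2 at day 3 averages 4.74, 7.14 and 5.07.

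The difference between the limb series itself changed between days. From day 1 to day 7 the difference in TK1 moved by 2.92 ± 0.58 (adjusted p = 0.0177). Its means were 4.34 innervated against 5.49 denervated at day 1, a difference not called, and 6.27 against 4.51 at day 7. The difference in CTSK moved by −3.61 ± 0.65 (adjusted p = 0.0089), from 5.72 innervated against 6.24 denervated to 8.36 against 12.5, a wider gap. TK1 lost this call without innervated day 7 replicate 1 (adjusted p = 0.0611). Mitosis genes had a median of 1.08 over these days, with 2 of 67 called and 41 when adjusted over the list alone (camera adjusted p = 8.46e-29, adjusted p = 0.13 with an estimated correlation). From day 1 to day 3 the hexokinase HK1 moved by −1.10 ± 0.21 (adjusted p = 0.00979), and epidermal differentiation genes had a median of 0.275, with 9 of 21 higher when adjusted over the list alone (adjusted p = 1.22e-06, 0.0715 with an estimated correlation). Without the 3 arrays of highest muscle signal that median was 0.165 and the adjusted p of HK1 was 0.194. With the arrays of the comparison alone HK1 had an adjusted p = 0.143 and CTSK 0.0726. The counts were 47 for day 3 against day 1, 121 for day 7 against day 1 and 11 for day 7 against day 3, and 15, 42 and 0 with the arrays of the comparison alone. They were sensitive to single arrays. The first was 25 and 85 without denervated and innervated day 1 replicate 1, 27 without innervated day 1 replicate 3, 23 without denervated day 3 replicate 3 and 31 without innervated day 3 replicate 2. The second was 41, 71 and 49 without denervated day 1 replicates 1, 3 and 4, 194, 46 and 20 without innervated day 1 replicates 1, 2 and 3, 51 and 57 without denervated day 7 replicates 1 and 3, and 14 and 73 without innervated day 7 replicates 1 and 2. The last was 18 and 7 without denervated day 3 replicates 1 and 2, 6 without innervated day 3 replicate 2, 7 and 25 without denervated day 7 replicates 1 and 2, and 6 without innervated day 7 replicate 1.

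Changes from day 0 also differed between limb and flank at day 1. In the innervated limb PTX3 changed by 7.23 ± 1.22 more than in the flank (adjusted p = 0.000357), ABI3BP by 5.46 ± 0.78 and MGP by 4.90 ± 1.05, while the change of COL11A1 had a difference of −2.15 ± 0.26 (adjusted p = 1.12e-06). SALL4 rose more in the innervated limb by 1.98 ± 0.24. The denervated limb differed from the flank in PTX3 by 6.27 ± 1.22 and ABI3BP by 4.30 ± 0.78, and in COL11A1 by −2.47 ± 0.26. The uninjured samples supply part of these values, since at day 0 limb minus flank was −3.65 for PTX3, −3.28 for ABI3BP, −1.58 for MGP and 2.33 for COL11A1. Compared directly at day 1 the innervated limb differed from the flank by 3.58, 2.17, 3.32 and 0.18 in these genes. The day 0 difference of COL11A1 thus exceeds its difference of changes in size, and the direct difference lies on the other side of 0. Matrix and fibroblast genes had 13 of 44 members with a higher change in the innervated limb, 22 when adjusted over the list alone, with a median of 0.883 (camera adjusted p = 2.64e-10, adjusted p = 0.144 with an estimated correlation), and 8 in the denervated limb, 14 when adjusted over the list alone (adjusted p = 3.16e-07, 0.245 with an estimated correlation). The innervated median of the fibrillar and provisional matrix list was 0.547 without flank day 0 replicate 3 and 0.569 without the 3 arrays of highest muscle signal. The mesenchymal filament gene VIM was higher by 1.30 ± 0.22 and the collagen hydroxylase P4HA1 by 1.71 ± 0.31. Endothelial genes had 5 of 15 higher, 6 when adjusted over the list alone (adjusted p = 0.000191, 0.12 with an estimated correlation), with EGFL7 at 1.94 ± 0.36. The endothelial list means of the innervated day 1 arrays were uneven, from −0.227 to 0.695, against −0.342 to −0.261 in the flank that day. Chaperones had 5 of 42 higher in the innervated limb (adjusted p = 9.39e-06, 0.0686 with an estimated correlation) and 6 in the denervated limb (adjusted p = 1.7e-07, 0.0253 with an estimated correlation), 7 and 8 when adjusted over the list alone. The chaperone list means at day 0 were 0.215 in the flank and −0.0532 in the limb. At day 1 they were 0.287 in the flank, 0.307 in the innervated limb and 0.363 in the denervated limb. By these means the day 0 difference between the regions supplied most of the chaperone difference. Muscle genes had 5 of 39 higher, 21 when adjusted over the list alone (adjusted p = 1.65e-12, 0.276 with an estimated correlation). The muscle list means of the innervated day 1 arrays ran from −0.0476 to 3.02, so this difference was uneven over arrays. There were 1052 probe sets for the innervated and 457 for the denervated limb, and 210 and 109 with the arrays of the comparison alone. Without flank day 0 replicate 4 they were 660 and 281, and without innervated day 0 replicate 2 they were 693 and 304. With the mean muscle signal as a covariate 515 and 226 passed. Subtracting each array's median moved the share of higher calls from 53.7% to 40.8% and from 58.9% to 41.9%, and the median change over all probe sets from −0.067 and −0.055 to −0.11 in both.

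Limb and flank also differed in their changes from day 0 at days 3 and 7. In the innervated limb at day 3 the calcium-binding protein gene CAPSL was higher in its change by 3.90 ± 0.42 (adjusted p = 1.23e-07), KAZALD1 by 3.02 ± 0.52 and SALL4 by 1.65 ± 0.24, and COL11A1 was lower by 2.91 ± 0.26. The denervated limb had KAZALD1 at 3.58 ± 0.52 and the guidance factor SLIT2 at 3.34 ± 0.43 above the flank. SQLE, an enzyme of cholesterol synthesis, was behind in its change, with a difference of −3.42 ± 0.73 in the innervated limb (adjusted p = 0.00463) and lost this call with the arrays of the comparison alone (adjusted p = 0.0845). At day 7 the change of CRABP1 was higher by 4.64 ± 0.69 (adjusted p = 4.41e-05) in the innervated limb, that of ALDH1A3, which makes retinoic acid, by 3.86 ± 0.84 (adjusted p = 0.00448), and that of SLIT2 by 2.64 ± 0.43. MAMDC2, a matrix proteoglycan, was lower by 3.01 ± 0.34 and the endothelial proteoglycan ESM1 had a difference of −2.52 ± 0.46. In the denervated limb at day 7 CTSK was higher in its change by 4.57 ± 0.65 (adjusted p = 1.62e-05), ALDH1A3 by 4.22 ± 0.84 and PTGES by 3.79 ± 0.51. For CAPSL, PTGES and COL11A1 the day 0 difference between the regions, −3.61, −3.36 and 2.33, supplies most of these values, and compared directly limb and flank differed by 0.285 in CAPSL (innervated, day 3), 0.435 in PTGES (denervated, day 7) and −0.58 in COL11A1 (innervated, day 3). Chaperones had 11 of 42 members higher in the innervated limb at day 7, 12 when adjusted over the list alone, and passed with either correlation (camera adjusted p = 2.64e-10 and 0.00818), with SDF2L1 at 1.30 ± 0.15 and HSP90B1 at 1.47 ± 0.18. Compared directly at day 7 these 2 genes differed by 0.655 and 0.352. In the denervated limb 8 were higher, 10 when adjusted over the list alone (adjusted p = 2.1e-06 and 0.0454). The counts were 632 at day 3 and 729 at day 7 for the innervated limb, and 791 and 762 for the denervated limb. With the arrays of the comparison alone they were 430 and 474, and 489 and 421. They were 396 at day 3 for the innervated limb without its day 0 replicate 2 and 464 at day 7 for the denervated limb without its day 7 replicate 1. Subtracting each array's median moved the share of higher calls in the innervated limb at day 3 from 62.5% to 49%, and its changes from day 0 at day 3 from 48.1% to 37.8%.

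Uninjured limb and flank epidermis differed in 872 probe sets. The homeobox gene EMX2 was higher in the limb by 3.37 ± 0.19 (adjusted p = 1.64e-15), DLX6, an appendage homeobox gene, by 1.72 ± 0.25 and HOXC5 by 1.24 ± 0.22. CHGA (chromogranin A) of neuroendocrine cells was higher by 2.79 ± 0.39, COL11A1 by 2.33 ± 0.18 and N-cadherin (CDH2) by 1.68 ± 0.24. CAPSL was higher in the flank by 3.61 log2 units (adjusted p = 5.73e-11), with a limb minus flank difference of −3.61 ± 0.30, and PTGES by a difference of −3.36 ± 0.36 and PEBP4 by −2.83 ± 0.26. Chaperones were higher in the flank, with 9 of 42 called and 13 when adjusted over the list alone, and 1 higher in the limb (camera adjusted p = 8.66e-07, adjusted p = 0.0362 with an estimated correlation), and HSP90B1 differed by −1.12 ± 0.13. Glycolysis genes had 4 of 21 higher in the flank, 5 when adjusted over the list alone (adjusted p = 0.000146, 0.144 with an estimated correlation). Muscle genes had 3 of 39 higher in the flank, 13 when adjusted over the list alone (adjusted p = 2.16e-05, 0.611 with an estimated correlation). The muscle gene ACTC1 differed by −4.84 ± 1.33 (adjusted p = 0.0273), a call that ended without flank day 0 replicates 2, 3 or 4 or innervated day 0 replicates 1 or 3 (adjusted p between 0.0567 and 0.127) and with the arrays of the comparison alone (0.0739). Matrix and fibroblast genes had 4 of 44 higher in the flank and 1 in the limb, 5 and 1 when adjusted over the list alone (adjusted p = 0.0218, 0.695 with an estimated correlation), a call that ended without flank day 0 replicates 3 or 4 or innervated day 0 replicates 1 or 4 (adjusted p between 0.0597 and 0.669), and its median of −0.0838 became −0.385, −0.144, 0.0387 and −0.0371 without flank replicates 1, 2, 3 and 4 and −0.169 without innervated replicate 3. Spiked-in poly-A control RNA was also unequal, with a mean over its probe sets of 0.657 in uninjured flank and −0.0685 in uninjured limb relative to all arrays. In total 380 probe sets were higher in the limb and 492 in the flank, 565 in all without flank day 0 replicate 4 and 563 without innervated day 0 replicate 2. With the arrays of the comparison alone the count was 136. Subtracting each array's median moved the share higher in the limb from 43.6% to 50.8%.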

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

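The tests of a lower share of epidermal cells, of muscle carried into samples and of dermis in the uninjured flank were chosen only after the results were seen, and so were the comparisons between days of the innervated against denervated difference.

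A difference between groups in their changes from day 0 drew attention in 6 comparisons of limb with flank. These were 1052, 632 and 729 probe sets for the innervated limb at days 1, 3 and 7, and 457, 791 and 762 for the denervated limb, with PTX3 and COL11A1 among the named genes of both limbs at day 1. Of the calls, 49%, 42.4% and 35.3% for the innervated limb and 60.6%, 41% and 40% for the denervated limb had a larger difference at day 0 than on the later day. The difference between innervated and denervated limb itself differed between days in 47 probe sets (day 3 against day 1), 121 (day 7 against day 1) and 11 (day 7 against day 3). Each comparison was repeated with the arrays divided in other ways, 35 divisions for 2 groups and 100 drawn at random for 4. Chance is an unlikely reason for the changes from day 0, where only 1 of 35 divisions, the real one, gave as many in each. That is the smallest share 35 divisions can give, and it was not adjusted over the comparisons, so chance is not excluded. The highest of the others were 1875, 637 and 714 against 7203, 5189 and 5336 in the innervated limb, 1118, 1468 and 1277 against 6845, 5297 and 5404 in the denervated limb, and 2759, 437 and 583 against 8271, 5485 and 4749 in the flank. Chance is unlikely to the same degree for innervated against denervated limb at day 3 (53, highest other 1) and day 7 (340, highest other 3). At day 1 chance cannot be excluded, since 7 of 35 divisions gave at least the 4 probe sets observed and the highest gave 22.

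For limb against flank at day 0 chance is also an unlikely reason, since only the real division of 35 reached the 872 (highest other 262). In the differences of changes, 1 of 100 divisions, the real one, gave as many for the innervated limb at day 1 (1052, highest other 492) and day 3 (632, highest other 455). The same was found for the denervated limb at day 1 (457, highest other 337) and day 3 (791, highest other 571). At day 7, 3 of 100 divisions reached the 729 of the innervated limb and 2 of 100 the 762 of the denervated limb. The highest others were 2190 and 781. The first of these exchanged all 4 day 0 labels between limb and flank, and the second exchanged 3, so they carry the day 0 difference of the regions, a structure of the samples. All divisions for differences of changes exchanged limb and flank arrays within a day, although the regions differed before injury. Such arrays are not interchangeable, so these divisions cannot decide whether chance explains the differences of changes. For the difference between days, 1 of 100 reached the 47 (highest other 31) and the 121 (highest other 14). Those divisions exchanged innervated and denervated arrays within a day, which differed at days 3 and 7, so they cannot decide about chance either. For day 7 against day 3, 4 of 100 reached the 11 (highest other 58). The count did not hold with the arrays of the comparison alone, so chance is not excluded there.

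Control RNA spiked into the labelling reaction was outside the main measurement. Its poly-A probe sets averaged 0.657 in uninjured flank (SD 0.182, n = 4) and −0.0685 in uninjured limb, relative to all arrays, and 31 of 45 control probe sets differed between groups. The 5′ probe set of the Thr control was at 6.44 ± 0.243 (SD) in uninjured flank, against group means of 4.61 to 4.95 elsewhere.

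Single arrays stood far from the other three of their group in 25 of the 341 groups examined, and chance marks about 1 in 20 groups. Among gene list means, centred over arrays, these were the epidermal differentiation genes of innervated day 1 replicate 1 (0.173, the others −0.0516 to −0.0269) and the matrix proteases of flank day 1 replicate 3 (0.103, others 0.212 to 0.222) and flank day 7 replicate 2 (−0.246, others −0.0117 to 0.0203). Matrix genes stood apart in flank day 3 replicate 2 (−0.0947) and innervated day 7 replicate 2 (−0.0211, others 0.5 to 0.572), mitosis genes in flank day 3 replicate 4 (0.717, others −0.299 to −0.191), and myeloid genes in denervated day 1 replicate 1 (−0.145) and flank day 3 replicate 3 (0.599). Lymphoid genes did so in denervated day 1 replicate 1 (0.151) and denervated day 7 replicate 4 (0.0497), erythrocyte genes in denervated day 1 replicate 4 (0.145) and innervated day 1 replicate 4 (0.083), and muscle genes in denervated day 1 replicate 1 (0.225, others 1.74 to 1.98). Further cases were endothelial genes in flank day 3 replicate 2 (−0.0562), TGF-beta genes in flank day 7 replicate 1 (0.119), oxidative phosphorylation genes in innervated day 3 replicate 3 (−0.0555) and denervated day 7 replicate 1 (−0.0063), and glycolysis genes in innervated day 3 replicate 4 (0.179). Actin genes stood apart in innervated day 0 replicate 1 (−0.33) and denervated day 1 replicate 1 (0.236). Among the plotted genes, CTSK was at 7.94 in innervated day 3 replicate 1 (others 5.64 to 5.83), CCNB1 at 6.67 in denervated day 1 replicate 2 (others 7.97 to 8.16), and TK1 at 6.69 in denervated day 3 replicate 2 (others 5.08 to 5.29). UAP1 was at 9.17 in flank day 1 replicate 2 and EREG at 9.99 in flank day 1 replicate 1 (others 9.33 to 9.41).

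Cell cycle genes were lower in the denervated than in the innervated limb at day 7, with a median over 119 members of 0.715 and 38 called. Leaving out any single array of the comparison kept the median at 0.583 or more, which argues against 1 array as the cause of the shift, although the number called ranged from 1 without innervated replicate 1 to 39 without innervated replicate 4. A lower share of epidermal cells in the denervated samples would raise the genes of every other cell type and lower epidermal ones, and the epidermal differentiation list differed by 0.0208 ± 0.0554 (SE). By the same mean scores (innervated minus denervated, SE over arrays) the myeloid list differed by −0.545 (SE 0.109), the erythrocyte list by −0.261 (SE 0.0717), the cartilage list by −0.267 (SE 0.0818), the endothelial list by −0.252 (SE 0.138), the fibroblast list by −0.0831 (SE 0.211) and the nerve list by −0.0613 (SE 0.0506), in its direction, and the antigen presentation list by 0.143 (SE 0.124), against it, the last 4 within 2 SE of 0, while muscle (0.0279, SE 0.0327) had scores near the lowest of all arrays at day 7, −1.32 to −1.2, and decides nothing. The level epidermal list argues against this explanation as the whole cause, unless regulation of its genes offset a lower share. Such regulation was not tested, and a rise of myeloid or other cells stays open. Slower division without a nerve supply stays open as a biological explanation, and which cells divide was not tested.

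Muscle transcripts were high in some limb arrays of day 1 and in denervated day 3 replicate 3. In the latter 89.7% of 39 muscle genes were above every other limb array of day 3, with CKM at 13.68 against at most 8.59 and PVALB at 14.16 against 6.37, and at least 97.4% of them had a higher mean at day 1 than at day 0 in either limb series. That mean was uneven, with scores of 2.77 and 3.02 in innervated day 1 replicates 3 and 4 but 0.364 and −0.0476 in replicates 1 and 2, against 1.04 in innervated day 0 replicate 2 and up to 1.94 in uninjured flank, and the innervated list call ended without the 3 highest arrays (adjusted p = 0.398). Muscle tissue carried into some of these samples is a candidate explanation. A labelling or hybridisation fault has nothing in its favour in the control RNA, since 3 of 3 of these arrays lay inside the spike-in range of the others. That range was wide, from −0.502 to 0.859 for the poly-A controls, so only a large fault could have shown. The amount of muscle under an amputation may depend on the level of the wound, which was not tested here, so a share of the day 1 signal that belongs to the healing surface stays open.

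Matrix genes rose more in the innervated limb than in the flank at day 1. More dermis in the uninjured flank samples would give matrix genes a higher level there at day 0, and their median was 0.0838 higher in the flank. The list mean was −0.506 in uninjured flank and −0.77 in uninjured limb. The SE of this difference of means was 0.297, so it cannot be told apart from no difference. Without the 3 arrays of highest muscle signal the median difference was 0.569 (SE of the list mean 0.479) with 8 members called in place of 13, so deeper tissue carried into limb samples together with muscle stays open. A labelling difference of the uninjured flank arrays is not needed for the direct difference at day 1, a median of 0.625 (SE of the list mean 0.262), but that spread leaves this open too. The wound type, amputation against punch, is an untested biological explanation.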

How the results depend on the processing

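The alternatives with muscle signal, and every alternative for the comparisons between days, were chosen after the data were seen, and the cause was not tested for any change below unless fewer arrays or genes explain it. Of 263 named genes, 1036 list members and 196 called lists, all kept the direction of their test in every alternative run except 6 list results in the alternatives with muscle signal. Without the 3 arrays of highest muscle signal, the day 3 against day 1 difference of innervated and denervated limb had a median of 1.06 for skeletal muscle, past the threshold, and 0.0467 for oxidative phosphorylation, and the matrix list in innervated against denervated limb at day 1 had 0.0137, both not past it. With the muscle covariate, which removes that signal by construction, the skeletal muscle list had medians of 0.0211 and −0.0966 in the flank at days 3 and 7 and −0.00145 in innervated against denervated limb at day 3, none past it. The direction compared is that of camera's test, so a median can keep its sign while the test turns. Median subtraction kept 263 genes, 1014 members and 193 lists called, quantile normalization 263, 1004 and 190, array weights 263, 1013 and 192, the replicate block 262, 1028 and 193, an intensity trend with a robust prior 254, 1023 and 196, the arrays of a comparison alone 203, 809 and 188, the muscle covariate 240, 935 and 167, and removal of the 3 muscle arrays 251, 971 and 174. Of lists, fry kept 137, an estimated correlation 29, the mean of probe sets 186 and removal of the dimmest probe sets 189. Leaving out single arrays ended the call at least once for 64 of 263 genes, 222 of 1036 members and 48 of 196 lists.

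Fitting only the arrays of a comparison leaves fewer residual degrees of freedom and takes the spread from those groups alone. Which of these moved the counts was not tested. This fit gave 0 and 11 probe sets for innervated against denervated limb at days 1 and 3 (main 4 and 53, and 1584 with an unadjusted p under 0.05 in limma at day 1). It gave 210 and 474 for innervated limb against flank at days 1 and 7, 109, 489 and 421 for denervated limb against flank, 136 at day 0, and 15, 42 and 0 for the differences between days (main 47, 121 and 11, the last with 1354 at an unadjusted p under 0.05). Array weights gave 776 for innervated against denervated limb at day 7, 961 for innervated limb against flank at day 3, and 188 and 62 for day 7 against days 1 and 3. A direct difference without day 0 gave 1250 and 1868 for the innervated and 1268 and 1442 for the denervated limb against flank at days 3 and 7. Quantile normalization gave 17 for innervated against denervated limb at day 1. For day 7 against day 3 (main 11) it gave 23, the intensity trend 22, removal of the dimmest probe sets 22 and the replicate block 18. The muscle covariate gave 7 at day 1 for innervated against denervated limb, and 515 and 226 for innervated and denervated limb against flank. Without the 3 arrays of highest muscle signal these were 15, 564 and 708, with 26 for innervated against denervated limb at day 3 and 29, 54 and 17 for the differences between days.

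Overlaps limited to called changes of at least 2-fold, a stricter rule, were 1448, 1019 and 1191 for the limb series at days 1, 3 and 7, 1158, 675 and 816 for innervated limb and flank, and 1131, 695 and 839 for denervated limb and flank. The day 0 arrays split 2 and 2 gave 2740 at day 3 for the limb series, with fewer arrays. Of the 196 list calls, 29 held with an estimated correlation.

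With single arrays left out, the counts for innervated limb days 1, 3 and 7 against day 0 ranged over 6496 to 7127, 4512 to 5016 and 4756 to 5117, for the denervated limb over 6112 to 6592, 4712 to 5140 and 4782 to 5145, and for the flank over 7431 to 8298, 4760 to 5038 and 4118 to 4507. Innervated against denervated limb ranged over 0 to 30, 28 to 65 and 72 to 326. Innervated limb against flank ranged over 660 to 1294, 396 to 693 and 506 to 824, denervated limb against flank over 281 to 680, 555 to 896 and 464 to 798, and limb against flank at day 0 over 563 to 927. The differences between days ranged over 23 to 85, 14 to 194 and 6 to 25, and the list calls over 183 to 205.

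The labels give the replicate numbers no meaning. After group means were removed, arrays of the same number correlated with a mean of 0.0386 and those of other numbers with −0.0129 (one-sided permutation p = 8e-04, a test added after the data were seen), and 17 of 44 arrays had their best match in their own number, 11 by chance (permutation p = 0.049). Only 61 of 220 pairs of the same number were over 0.1, so the numbers were not taken to pair the samples, and this weak link is a hint from the data whose cause was not tested. The alternative for values on a linear scale was not run. Signal over background limits dim probe sets, and without the dimmest 25% none of the 259 named genes that stayed lost its call.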

Other observations

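The tests of whether the cholesterol, osteoclast and sugar nucleotide genes move as sets were chosen only after their first members were seen, and so were the direct comparisons of cholesterol genes and, for chaperones, the test in the denervated limb, the means and the removal of single day 7 arrays, while the chaperone test in the innervated limb was chosen before.

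SQLE, LSS and CYP51A1, enzymes of cholesterol synthesis, stood out in the change of the innervated limb against the flank at day 3. In the flank SQLE rose by 2.59 ± 0.51 at day 1 (adjusted p = 8.46e-05) and by 1.64 at day 3 (adjusted p = 0.0148), and at day 3 its log2 level in the innervated limb was 7.69, against 9.47 at day 0. The cholesterol synthesis list of 17 genes had medians from day 0 of −0.82 (innervated), −0.708 (denervated) and 0.185 (flank) at day 3, and of −0.713, −0.89 and −0.333 at day 7, when no member was called in the difference of changes of either limb and the flank. At day 0 the limb was higher by a median of 0.328 (SE of the list mean 0.487). With SQLE, LSS and CYP51A1 removed, the other 14 genes had a median of −0.626 in the difference of changes at day 3, and limma's camera gave a p of 1.66e-05, or 0.0504 with an estimated correlation. Compared directly at day 3 these 14 genes were lower in the limb, with a median of −0.433 (SE of the list mean 0.0497). A lower synthesis of cholesterol in limb wounds than in flank wounds at day 3 may underlie it, but SQLE, CYP51A1 and LSS all lost their calls with the arrays of the comparison alone (adjusted p = 0.0845, 0.178 and 0.123), CYP51A1 and LSS also when single arrays were left out, and sterols were not measured here.

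CTSK and ACP5, both enzymes of osteoclasts, were higher in the denervated than in the innervated limb at day 7. Of a list of osteoclast and bone resorption genes, 7 were lower in the innervated limb, and in the denervated limb 11 rose from day 0 and 1 fell. The rise was not confined to the denervated limb, since by day 7 the flank wound had 7 up and 1 down. The innervated limb had 6 up and 1 down. In the change of the denervated limb against the flank at day 7, 3 were higher and 1 lower (camera adjusted p = 0.00644, 0.122 with an estimated correlation). Without CTSK, ACP5, CKB and SNX10, which the naming rule had picked, 16 of 20 members remained, 4 of these were called lower, and limma's camera gave a p of 7.99e-07, or 3.42e-05 with an estimated correlation. A resorbing phagocyte at the denervated stump may be a source of these transcripts. Macrophages share many of them, and a cell count was not part of the data.

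GFPT2, UAP1 and UGDH, which lead to the sugar nucleotides of hyaluronan, were higher in the innervated limb at day 3. A wider set of UDP-sugar and hyaluronan genes kept 18 of 21 members once those genes were removed, with 2 called and a median of 0.045. The p of limma's camera for that set was 0.0515, which did not pass 0.05. Retinoid genes as a list did not pass in innervated against denervated limb at day 7 (adjusted p = 0.955), with 1 member higher, although CRABP1 was called.

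Chaperone genes fell in the flank from day 0 to day 7, and the limb changed differently. If a high level in the uninjured flank samples alone were the reason, limb and flank would be level at day 7. The innervated limb was higher there by a median of 0.148, against a median difference of changes of 0.171 (0.103 without innervated day 0 replicate 3). With each day 7 array left out it stayed between 0.12 and 0.17, which argues against that reason alone. By means it was 0.144 (SE 0.0295) against 0.412. At day 0 the list mean was 0.215 in the flank and −0.0532 in the innervated limb, so by this measure the day 0 difference supplied the larger part. In the denervated limb the median was 0.0788 against 0.09 (0.136 without innervated day 0 replicate 4) and the mean 0.016 (SE 0.0451) against 0.284, which leaves that reason open there.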
